A study of Rattus norvegicus with 6 samples.

How the data were processed

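RNA from 6 cultures of GH4C1 cells was labelled with biotin and hybridised to Affymetrix rat expression arrays, 1 array per culture, per the labels' protocols. The deposited values are intensity values, 1 signal per probe set on a linear scale, made by the authors with MAS5, per the submitters' processing notes. Its version, the background settings and the detection calls are not given in the sources used here. From the values, each array had been scaled so that its mean after trimming 2% at each end was 100. Such scaling ties all signals of an array to its bright probe sets and can shift dim ones between arrays. MAS5 signals of dim probe sets scatter widely: the median SD of log2 signal within a group was 0.109 for 4925 probe sets at or above a signal of 200 and 0.285 for tested ones below it.

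Groups were taken from the sample labels, 3 control and 3 POU1F1(R271W) arrays, and 1 comparison was made. Gene symbols came from a platform annotation table, updated by Entrez ID through a RefSeq gene table of the GRCr8 assembly. Of 31042 non-control probe sets, 20826 had 1 symbol, 436 had several and 9780 were not in the table and are unnamed here. No coordinates were used. Among the 2940 called probe sets 2428 had 1 symbol and 512 had none or several.

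Signals were converted to log2 without further scaling and tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, group as the term), with Benjamini-Hochberg adjustment and a threshold of 0.05. Control probe sets were left out, and a filter kept those whose mean log2 signal over 6 arrays was at or above the 40th percentile (a signal of 11.2), which left 18625. A gene was represented by its probe set with the highest mean among those with a single symbol. The 20 gene lists were tested with camera at a preset correlation of 0.01 and adjusted over the lists. None of the lists called lower (unfolded protein response, immediate early genes, hypoxia and glycolysis) passed when the correlation was estimated. A few genes belong to more than 1 list. Affymetrix control probe sets were compared by exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

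The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. Named were Pou1f1 and every measured POU1F1 target, the 12 genes higher and 12 lower with the largest absolute log2 change among those past the threshold whose arrays did not overlap between groups, and up to 4 members with the smallest p in each other list. Provisional symbols were to be skipped, and 0 were. Probe sets of a named gene that differed in sign were named. Not every member the rule allows is described.

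On simulated data with the real means and spreads, 200 probe sets were changed among 18625 tested. The test recovered 15 of 99 tested changes of 0.5 and 40 of 96 tested changes of 1 on the log2 scale, and 3 of its 58 calls were unchanged probe sets. A simulated list of 27 genes lowered by 0.3 among 10189 genes was found by camera, with 0 other lists called. With an estimated correlation it also passed (camera adjusted p = 0.00711, against 1.2e-35 at the preset correlation). Probe sets were drawn independently, whereas real lists had estimated correlations of up to 0.791 (ribosomal proteins). The 0 other calls therefore do not show how often camera calls a list of correlated genes by mistake. The simulation had fewer true changes than the real comparison appears to have, and recovery depends on that number.

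Alternatives were quantile normalization, centring on the median or the 75th percentile, no filter or a filter at the 60th percentile, a floor or an offset at the 20th percentile of all signals (3.72), eBayes without the trend or robust, array weights, a replicate block, 1 probe set per gene, a fold of at least 1.5, an estimated correlation, the mean over probe sets, other probe sets of a gene, and leaving out each array in turn.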

Results

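Gene expression was measured in GH4C1 cells, a rat pituitary tumour line of the somatolactotroph type, which makes growth hormone and prolactin. The cells had been transduced with lentiviral vectors at a multiplicity of infection of 5 and were grown for 4 days. Of the 6 cultures, 3 carried POU1F1(R271W), a form of the pituitary transcription factor POU1F1 that the series title calls a dominant negative mutant, and 3 were controls. The design text names a vector with EGFP alone as the control and an EGFP reporter on the mutant construct. Each culture was hybridised to 1 Affymetrix rat array, and the labels call the replicates biological. The array table held 31099 probe sets, of which 57 were Affymetrix controls. Median signals were 22.9, 22.7 and 22.4 on the control arrays and 26.9, 25.7 and 25.5 on the R271W arrays, and the number of arrays limits the precision of every value. Correlations across probe sets ran from 0.949 to 0.957 between arrays of the same group and from 0.933 to 0.944 between arrays of different groups.

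The comparison asks which transcripts differ when the mutant factor is present, and the first genes read were Pou1f1 itself and its known targets. Prl, which encodes prolactin, fell from a MAS5 signal of 4332 ± 188 (SD, n = 3) in controls to 3175 ± 171 (n = 3) in R271W cells. Its log2 fold change was -0.45 (95% confidence interval -0.59 to -0.31, limma adjusted p = 0.00048), and all 3 R271W arrays lay below all 3 controls. Pou1f1 fell from 2301 ± 90.1 to 1836 ± 86.2, a log2 fold change of -0.33 (interval -0.47 to -0.18, adjusted p = 0.00486), and its other probe set gave -0.35. Whether either Pou1f1 probe set detects the transduced transcript is not known from the sources used here, so this value does not check the transgene. Gh1, which encodes growth hormone, had signals of 6443 ± 349 and 6338 ± 867, a log2 fold change of -0.03 (interval -0.22 to 0.15, adjusted p = 0.853). Gh1 lay near the top of the arrays, whose highest signals ran from 7354 to 8832, so compression of its difference cannot be read from these values. Thrb, a thyroid hormone receptor gene, had a log2 fold change of 0.20 with an adjusted p of 0.0862, which became 0.00835 under quantile normalization and 0.0437 without R271W replicate 1. Median centring moves every log2 change by about -0.20, which is the size of this change, so the rise depends on the scaling. The 3 other tested probe sets of Thrb read 0.08, 0.07 and 0.08 with arrays that overlapped (adjusted p = 0.564, 0.841 and 0.853). Tshb and Ghrhr lay below the signal filter and were not tested. Of the 4 tested members of the POU1F1 target list, 2 fell and 0 rose, with 2 lower and 1 higher adjusted over the list alone, and the list as a set did not pass (camera adjusted p = 0.28). With eBayes fitted without its intensity trend, the adjusted p of Prl was 0.0583 and that of Pou1f1 was 0.107.

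**Figure D1:**
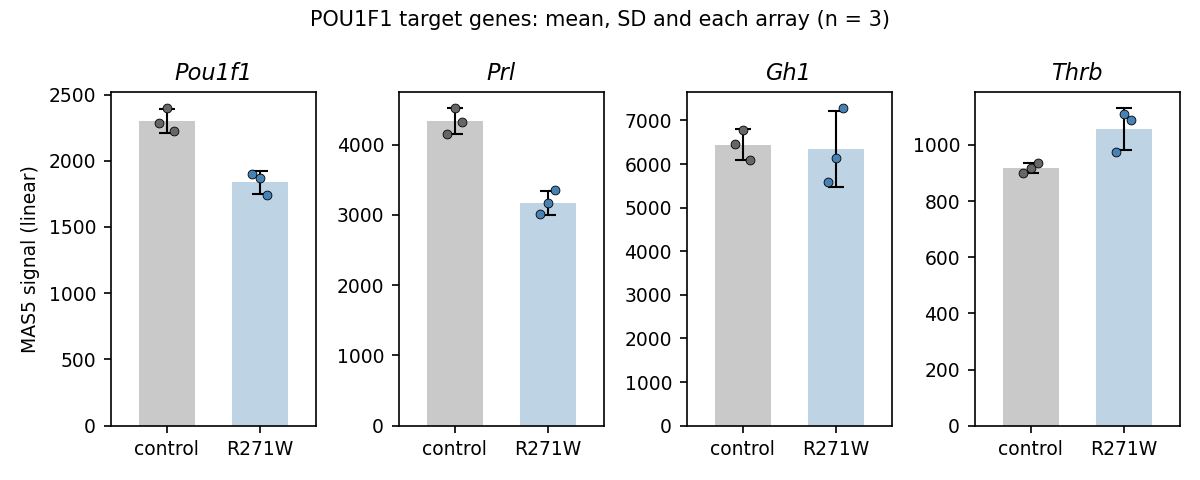
MAS5 signals, on linear axes that start at 0, of Pou1f1 and 3 of its target genes in control and R271W cells; bars are means, error bars SD and points single arrays (n = 3 per group). The R271W arrays lie below the controls for Pou1f1 and Prl, overlap them for Gh1 and lie above them for Thrb, whose adjusted p was 0.0862.

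Across the transcriptome, 1596 probe sets rose and 1344 fell in R271W cells among 18625 tested, which is 15.8% of them at an adjusted p under 0.05. On a per-gene basis 1001 genes rose and 911 fell among 10143. Changes of at least 2-fold were seen for 337 probe sets that rose and 104 that fell. Of all tested probe sets, 33.9% had groups that did not overlap, against 10% by chance. That 10% assumes no offset between the groups. The median signals of the arrays did not overlap either (22.4 to 22.9 against 25.5 to 26.9), and such an offset raises the share by itself. The split between directions depended on how arrays were scaled: 54.3% of calls were higher with the deposited scaling, 50% with quantile normalization, 36.9% (1124 higher, 1923 lower) with 75th percentile centring and 18.9% (730 higher, 3132 lower) with median centring, which moves the median of all log2 changes by -0.20. Without the intensity trend the counts were 634 and 431. Leaving out R271W replicate 2 left 1000 that rose. The hybridisation spikes, which are added to every sample, also read higher on the R271W arrays by 0.23 on the log2 scale.

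**Figure D2:**
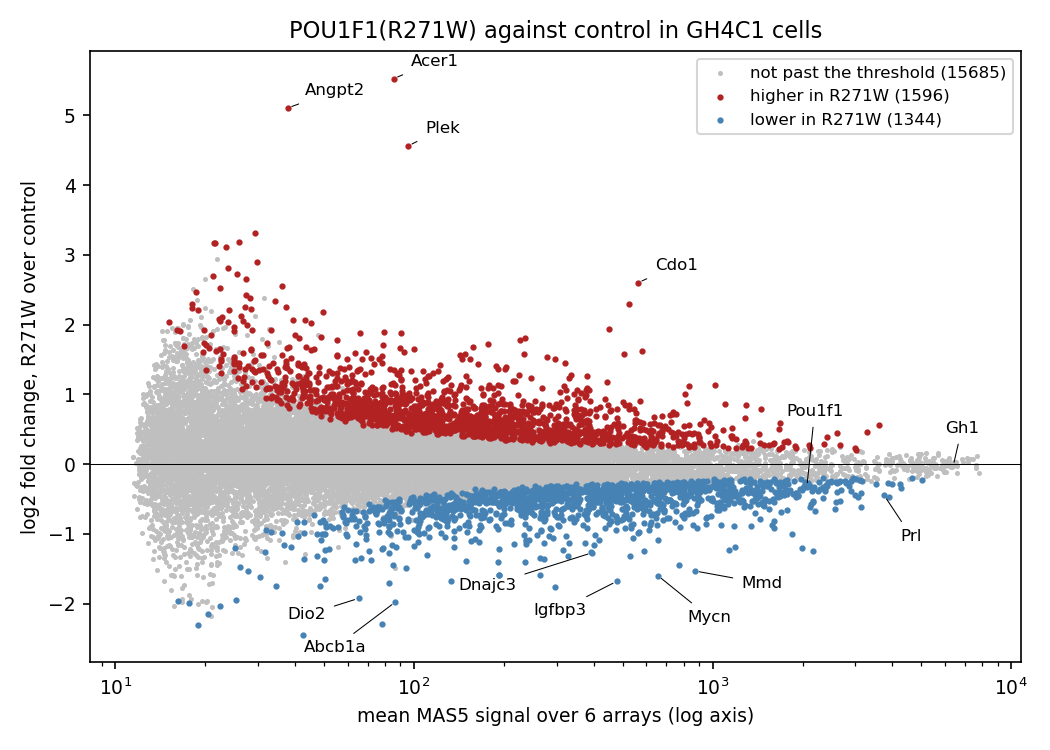
Log2 fold change of R271W over control against the mean MAS5 signal over 6 arrays (log axis), 1 point per tested probe set; red points (1596) rose, blue points (1344) fell and grey points did not pass an adjusted p of 0.05. Acer1, Angpt2 and Plek have the labelled changes of 5.53, 5.11 and 4.56, at low control signals, while Prl and Pou1f1 changed less at high signals.

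The genes that rose furthest included Cdo1, which encodes cysteine dioxygenase, an enzyme of cysteine breakdown. Its signal went from 159 ± 16.7 to 966 ± 88.9 (n = 3 each), a log2 fold change of 2.60 (SE 0.10, adjusted p = 1.84e-08). The other 11 of the 12 largest increases began at control signals of 2.91 to 13.1, where the size of a fold is poorly set. Acer1, an alkaline ceramidase gene, rose from 7.25 ± 9.43 to 164 ± 18.6 (log2 5.53, or 4.69 with a floor of 3.72 under the signals and 4.27 with that value added). Angpt2, which encodes angiopoietin-2, rose from 2.91 ± 2.79 to 72.7 ± 14.4 (log2 5.11, or 4.04 and 3.59). Plek, which encodes pleckstrin, rose from 12.8 ± 15.6 to 179 ± 28.1 (log2 4.56, or 4.44 and 3.86). C9, a terminal complement component, rose by 3.18 on the log2 scale, Lmod3, an actin-binding leiomodin of muscle, by 3.16, and Tox, an HMG-box factor, by 3.11. Ypel4 rose by 2.90, Sypl2 by 2.70, Aldoc, the brain-type aldolase, by 2.55, Ggnbp1 by 2.52 and Aifm2 by 2.47. With the value added, these 8 genes had log2 changes between 1.72 for Aifm2 and 2.43 for C9. In all 12 genes every R271W array lay above every control array, which the naming rule required. Other probe sets of Lmod3 (-0.47) and Sypl2 (-0.51) had the opposite sign without passing. The call of Aifm2 ended without control replicate 1 (adjusted p = 0.0942) or 2 (0.0822), and that of Ypel4 without R271W replicate 1 (0.071), 2 (0.13) or 3 (0.0585). Aifm2 also did not pass under quantile normalization (0.0666), under median centring (0.0504) or without the filter (0.0719). Without the intensity trend the adjusted p was 0.0813 for Lmod3, 0.182 for Ypel4, 0.0645 for Sypl2, 0.0808 for Aldoc and 0.13 for Aifm2.

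The genes that fell furthest included several with strong control signals. Igfbp3, a binding protein for insulin-like growth factors, fell from 728 ± 24.1 to 227 ± 7.87, a log2 fold change of -1.68 (SE 0.08, adjusted p = 1.27e-07). Mycn, a MYC-family transcription factor gene, fell from 988 ± 51.2 to 326 ± 30.9 (log2 -1.60, adjusted p = 2.5e-07). Mmd fell from 1299 ± 12.1 to 449 ± 19.8 (log2 -1.53, adjusted p = 1.05e-07). Ctnna2, a neural catenin gene, fell from 395 ± 21.0 to 133 ± 26.8 (log2 -1.59), and Deptor, which encodes an inhibitor of mTOR, from 289 ± 31.5 to 97.4 ± 23.6 (log2 -1.59). Abcb1a, a multidrug efflux pump, fell by 1.98 on the log2 scale and by 2.29 on its other probe set. Dio2, the deiodinase that activates thyroid hormone, fell from 103 ± 17.5 to 27.2 ± 4.85 (log2 -1.93). The remaining 5 were Il4r (-2.03), Mcub (-1.96), Hapln2 (-1.75), Nmral1 (-1.67) and Tnfsf10 (-1.54), the last of which encodes the death ligand TRAIL. In all 12 genes every R271W array lay below every control array, which the naming rule required. Another probe set of Hapln2 read 1.02 without passing. Leaving out a single array ended 4 of these calls. It also lowered the calls over all probe sets, from 2940 to between 2042 and 2673. A lost call thus need not mean that 1 array carried it. Where the calls ended, the log2 fold change was -1.46 to -1.95 for Il4r and -1.48 to -1.82 for Nmral1. The adjusted p was 0.06 for Mcub without control replicate 1 and 0.053 for Tnfsf10 without control replicate 3. For Il4r it was 0.094, 0.0974 and 0.0539 without control replicate 2, control replicate 3 and R271W replicate 1. For Nmral1 it was 0.0926, 0.129 and 0.0759 without control replicates 1, 2 and 3. Without the intensity trend the adjusted p was 0.0917 for Il4r, 0.0701 for Hapln2 and 0.24 for Nmral1, which was 0.196 with robust eBayes.

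Genes of the unfolded protein response encode chaperones and quality-control factors of the endoplasmic reticulum and the regulators that respond to stress there. Of 27 tested members 18 fell and 0 rose, or 19 and 0 adjusted over the list alone, with a median log2 fold change of -0.31 (camera adjusted p = 2.08e-11). With an estimated correlation between genes the list did not pass (adjusted p = 0.207). Of the 9 members that did not pass, 4 read above 0, which were Ddit3 (0.20), Chac1 (0.17), Asns (0.06) and Ero1a (0.01). Dnajc3, a co-chaperone that also restrains the kinase PERK, fell from 558 ± 18.5 to 231 ± 9.97 (log2 -1.27, SE 0.09). Creld2 fell from 1655 ± 125 to 724 ± 76.6 (log2 -1.19), Sdf2l1 from 1012 ± 21.1 to 541 ± 6.17 (log2 -0.90) and Manf from 2563 ± 68.0 to 1676 ± 26.7 (log2 -0.61). In these 4 genes every R271W array lay below every control array, as in 905 of the 911 genes called lower. Without the intensity trend 7 members fell. On the same arrays the hybridisation spikes read 0.23 higher in R271W cells on the log2 scale, and the beta-actin ratio of 3' to 5' signal was 1.96 ± 0.099 against 1.82 ± 0.0076 in controls, without overlap. The poly-A spikes, the beta-actin ratio of 3' to middle signal and both GAPDH ratios overlapped between the groups.

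Immediate early genes, which respond quickly to signalling, were lower as a set (median log2 fold change -0.18, camera adjusted p = 0.0086), with 6 of 27 members that fell and 1 that rose, or 9 and 2 adjusted over the list alone. The set did not pass with an estimated correlation (adjusted p = 0.225). Dusp1, a phosphatase of MAP kinases, fell from 751 ± 18.9 to 381 ± 30.0 (log2 -0.98), and the AP-1 genes Fosl2 and Fosl1 had log2 fold changes of -1.38 and -0.97. Klf10, a zinc-finger gene, rose by 0.65 on the log2 scale. Under median centring 11 members fell and 1 rose, without the intensity trend 4 fell and 0 rose, and 4 fell without control replicate 2 or 3. The hybridisation spikes (0.23 higher) and the beta-actin ratio of 3' to 5' signal (1.96 against 1.82) also separated the groups on these arrays, while the poly-A spikes and the other beta-actin and GAPDH ratios did not.

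The list of hypoxia and glycolysis genes had 11 of 24 members that fell and 2 that rose, or 12 and 2 adjusted over the list alone, with a median log2 fold change of -0.17 (camera adjusted p = 0.00116). It too did not pass with an estimated correlation (adjusted p = 0.693). P4ha2, a collagen prolyl hydroxylase subunit, fell from 467 ± 18.3 to 189 ± 17.4 (log2 -1.31), and Hk2, the inducible hexokinase, from 125 ± 34.1 to 45.1 ± 5.37 (log2 -1.44). P4ha1 and Pdk1, a kinase that inhibits pyruvate dehydrogenase, had log2 fold changes of -0.60 and -0.47. Aldoc and Ndrg1 were the members that rose, by 2.55 and 0.28 on the log2 scale, and Ndrg1 is named here after its value was seen. The adjusted p of Ndrg1 was 0.0481 and its call depended on the settings. It did not pass under median centring (0.09, adjusted p = 0.586), 75th percentile centring (0.184), no filter (0.0652), array weights (0.0583) or a replicate block (0.0639), or without the intensity trend (0.201). It also did not pass without control replicate 2 (0.177), control replicate 3 (0.131), R271W replicate 1 (0.101) or R271W replicate 3 (0.119). Its other probe set read 0.37 without passing (adjusted p = 0.203). Without the intensity trend 2 members fell and 0 rose. Here too the hybridisation spikes (0.23 higher) and the beta-actin ratio of 3' to 5' signal (1.96 against 1.82) separated the groups, while the poly-A spikes and the other beta-actin and GAPDH ratios did not.

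**Figure D3:**
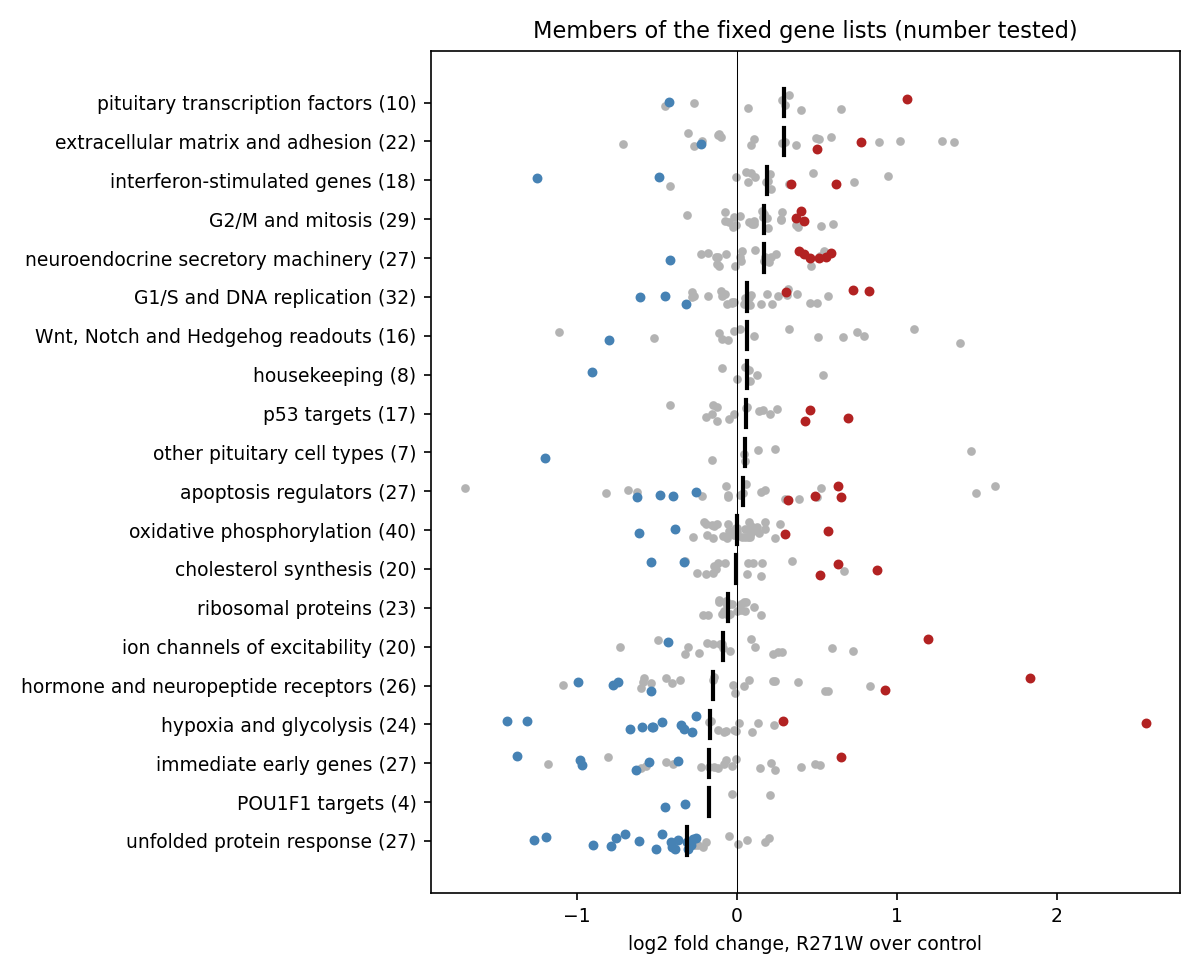
Log2 fold change of R271W over control for each tested member of the 20 gene lists, with the number tested in brackets; red points rose, blue points fell, grey points did not pass and black bars are list medians. The unfolded protein response list has the lowest median, -0.31. The zero line assumes the deposited scaling, and median centring moves every value by about -0.20, which takes several medians near 0 below it.

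With the main settings no list tied to pituitary identity and secretion passed camera, though single members passed by limma. Over all genes, 1001 rose and 911 fell among 10143. Among 10 pituitary transcription factor genes 1 rose and 1 fell, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.885). Zbtb20, a zinc-finger factor of lactotroph development, rose from 243 ± 21.9 to 512 ± 98.3 (log2 1.06). Sox2, a progenitor factor, had a log2 fold change of -0.43, with an adjusted p of 0.0196 that became 0.0685, 0.0624 and 0.0876 without control replicate 1, control replicate 2 and R271W replicate 2. Its other probe sets were dimmer: one fell from 33.1 ± 3.43 to 7.67 ± 2.54 (log2 -2.15, adjusted p = 0.00798), and the others read -0.89 (adjusted p = 0.132) and -1.11 (adjusted p = 0.694) with arrays that overlapped. Among 26 hormone and neuropeptide receptor genes 2 rose and 4 fell, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.278). The somatostatin receptor gene Sstr1 fell from 1060 ± 67.8 to 730.2 ± 23.6 (log2 -0.54). Another Sstr1 probe set also fell, from 190 ± 27.1 to 130 ± 17.5 (log2 -0.55, adjusted p = 0.02), and the remaining one, at signals of 1.29 and 1.41, read 0.26 without passing (adjusted p = 0.935). The growth hormone receptor gene Ghr fell from 143 ± 15.4 to 71.9 ± 5.94 (log2 -0.99). Sstr2 had a log2 fold change of -0.78 (-0.30 on another probe set that did not pass), with an adjusted p of 0.0509 without control replicate 2. Rxrg, a retinoid X receptor gene, rose from 21.7 ± 5.45 to 76.2 ± 13.6 (log2 1.83), while another, dimmer probe set read -1.11 without passing. Among 7 tested markers of other pituitary cell types 0 rose and 1 fell, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.885). The one that fell was Dcn, the proteoglycan decorin, from 2770 ± 90.4 to 1205 ± 37.2 (log2 -1.20).

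In the neuroendocrine secretory list 6 of 27 genes rose and 1 fell, or 7 and 1 adjusted over the list alone. Under median centring 4 rose and 5 fell, and without the intensity trend 1 rose and 0 fell. The median was 0.17, or -0.03 under median centring, and camera gave an adjusted p of 0.18, which became 0.011 under quantile normalization. The granule protein genes Chgb, Resp18 and Vgf rose by 0.46, 0.56 and 0.51 on the log2 scale, and Rab3d, a vesicle GTPase gene, by 0.59. Chgb went from 2779 ± 146 to 3815 ± 94.0. Among 20 ion channel genes 1 rose and 1 fell, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.885). The potassium channel gene Kcna4 rose from 76.3 ± 10.5 to 175 ± 25.7 (log2 1.19). Kcnd3 had a log2 fold change of -0.43 at an adjusted p of 0.0492, with 2 other probe sets at 1.31 and 0.24 that did not pass, and its adjusted p was 0.119, 0.094, 0.135, 0.127 and 0.127 without control replicates 1, 2 and 3 and R271W replicates 1 and 2. The potassium channel gene Kcnj6 and the calcium channel gene Cacna1d had log2 fold changes of -0.73 (adjusted p = 0.148) and -0.31 (adjusted p = 0.246). Their other probe sets were dim and did not pass, at 0.19, -0.10 and 1.73 for Kcnj6 and 0.59 and 1.40 for Cacna1d.

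With the main settings no list of growth and death genes passed camera, and only the G1/S and apoptosis lists had single members called in both directions. In the G1/S and DNA replication list 3 of 32 genes rose and 3 fell, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.887). Prim2, a primase subunit gene, rose by 0.73 on the log2 scale and Slbp, which encodes the histone stem-loop binding protein, by 0.82, with 2 dim probe sets at 0.34 and 0.00 that did not pass. Ccne2, which encodes cyclin E2, had a log2 fold change of -0.61, and its dimmer probe set read 0.23 without passing. In the G2/M list 3 of 29 genes rose and 0 fell, or 1 and 0 adjusted over the list alone. Camera gave an adjusted p of 0.134, which became 0.046 without the filter. The 3 that rose were Top2a (0.37), Mad2l1 (0.42) and Aurka (0.40), and under median centring their adjusted p values were 0.235, 0.268 and 0.326. Other probe sets that did not pass read 0.21 for Top2a and 0.31 and 0.14 for Mad2l1. Each call also ended without some single arrays. For Top2a the adjusted p was 0.0625 without control replicate 2 and 0.0682 without R271W replicate 2. For Mad2l1 it was 0.0936, 0.0888, 0.0825, 0.088 and 0.13 without control replicates 1, 2 and 3 and R271W replicates 1 and 3. For Aurka it was 0.121, 0.0768, 0.0873, 0.105 and 0.13 without control replicates 1, 2 and 3 and R271W replicates 2 and 3.

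Among 17 p53 targets 3 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.887). Plk2, a polo-like kinase gene, rose from 168 ± 10.8 to 272 ± 17.0 (log2 0.70). Xpc (0.45) and Sesn1 (0.42) did not pass under median centring (adjusted p = 0.146 and 0.26). Mdm2, which encodes the ubiquitin ligase of p53, had a log2 fold change of -0.19 (adjusted p = 0.0859) with all 3 R271W arrays below the controls. It passed as lower under median centring (-0.39, adjusted p = 0.00283) and 75th percentile centring (-0.28, adjusted p = 0.0248). Xpc had an adjusted p of 0.0563 without control replicate 3. Sesn1 had 0.106, 0.106, 0.101, 0.169 and 0.133 without control replicates 1, 2 and 3 and R271W replicates 1 and 2. Among 27 apoptosis regulators 4 rose and 4 fell, or 7 and 5 adjusted over the list alone (camera adjusted p = 0.887). The pro-apoptotic genes Bok and Bad rose by 0.65 and 0.63 on the log2 scale, and the survival genes Mcl1 and Bcl2 had log2 fold changes of -0.48 and -0.63. The other 4 called members, named after their values were seen, were the survival gene Xiap (0.49) and the death receptor gene Tnfrsf1a (-0.40), with the related BH3-type genes Bnip3l (0.32) and Bnip3 (-0.26). None of these 4 passed without the intensity trend, with adjusted p values of 0.0518, 0.0872, 0.159 and 0.173. Under median centring Xiap (0.141) and Bnip3l (0.445) did not pass, nor did Bnip3l under 75th percentile centring (0.126) or Bnip3 under quantile normalization (0.168). With a replicate block the adjusted p was 0.0586 for Bnip3l and 0.0502 for Bnip3. Leaving out single arrays ended each call at least once, with adjusted p values of 0.056 to 0.0714 for Xiap, 0.0506 to 0.0849 for Tnfrsf1a, 0.051 to 0.11 for Bnip3l and 0.0564 to 0.093 for Bnip3 where they did not pass. The other probe set of Bok read 0.20 (adjusted p = 0.384), with arrays that overlapped. Bcl2 had an adjusted p of 0.0573 without control replicate 1 and 0.0668 without control replicate 2.

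Among 18 interferon-stimulated genes 2 rose and 2 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.885). Bst2, which encodes the virus-tethering protein tetherin, fell from 3057 ± 193 to 1293 ± 183 (log2 -1.25), and the immunoproteasome gene Psmb8 had a log2 fold change of -0.49. The 2 that rose were Psmb9, another immunoproteasome gene, at 0.34 (adjusted p = 0.037), and Eif2ak2, which encodes the kinase PKR, at 0.61 (adjusted p = 0.0489). Under median centring their adjusted p values were 0.415 and 0.168, and under 75th percentile centring 0.124 and 0.0824. Leaving out any single array ended both calls, with adjusted p values of 0.0569 to 0.128 for Psmb9 and 0.0695 to 0.179 for Eif2ak2. Under quantile normalization Psmb9 passed (adjusted p = 0.0491) and Eif2ak2 did not (adjusted p = 0.129). Among 20 cholesterol synthesis genes 3 rose and 2 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.885), with Tm7sf2, a sterol reductase gene, at 0.87 and Insig1, a regulator of sterol sensing, at -0.54. Among 22 matrix and adhesion genes 2 rose and 1 fell, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.543). The hyaluronan receptor gene Cd44 rose by 0.77 and the protease inhibitor gene Timp2 by 0.50 on the log2 scale, with another probe set of Timp2 at 0.27 that did not pass. Among 16 Wnt, Notch and Hedgehog readouts 0 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.991), which was Bambi, a pseudoreceptor of TGF-beta signalling, at -0.80.

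Among 40 oxidative phosphorylation genes 2 rose and 2 fell, also adjusted over the list alone. The median was 0.00 and the camera adjusted p 0.885, against a median of 0.10 (adjusted p = 0.0401) under quantile normalization and -0.20 (adjusted p = 0.0359) under median centring. Ndufb3, a complex I subunit gene, fell from 1269 ± 23.1 to 831 ± 12.0 (log2 -0.61). Among 23 ribosomal protein genes 0 rose and 0 fell by limma, also adjusted over the list alone. Their median was -0.06 (camera adjusted p = 0.49), -0.03 under quantile normalization, -0.14 under 75th percentile centring and -0.25 under median centring, where the list passed (adjusted p = 0.00867). It also passed without R271W replicate 3 (adjusted p = 0.00171). Among 8 housekeeping genes 0 rose and 1 fell, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.885), with a median of 0.06 that was -0.14 under median centring and -0.02 under 75th percentile centring. The gene that fell was Tfrc, the transferrin receptor, from 2089 ± 50.1 to 1114 ± 95.8 (log2 -0.91).

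Among the list members named above, the calls of Klf10, P4ha1, Pdk1, Sox2, Chgb, Resp18, Vgf, Kcnd3, Prim2, Slbp, Ccne2, Top2a, Mad2l1, Aurka, Xpc, Sesn1, Mcl1, Psmb8, Psmb9, Eif2ak2, Insig1, Timp2 and Bambi ended without the intensity trend. Their adjusted p values then lay between 0.0505 for Eif2ak2 and 0.144 for Sesn1.

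The Affymetrix control probe sets gave a view of labelling and RNA quality. The mean log2 signal of the hybridisation spikes was 8.93 ± 0.12 (n = 3) on control and 9.17 ± 0.11 (n = 3) on R271W arrays, a two-sided exact permutation p of 0.1, which is the smallest that 3 against 3 allows. The poly-A spikes read 4.55 ± 0.11 and 4.66 ± 0.15 (exact permutation p = 0.4). The beta-actin ratio of 3' to 5' signal was 1.82 ± 0.0076 in controls and 1.96 ± 0.099 in R271W cells (exact permutation p = 0.1), and its ratio of 3' to middle signal was 1.32 ± 0.0186 and 1.34 ± 0.111 (exact permutation p = 0.8). The GAPDH ratio of 3' to 5' signal was 0.993 ± 0.0599 and 0.981 ± 0.0153 (exact permutation p = 0.8), and its ratio of 3' to middle signal was 1.17 ± 0.028 and 1.14 ± 0.0207 (exact permutation p = 0.3). No value of this kind can pass 0.05 in this design.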

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

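The tests on the spikes and on the probe sets below the filter, and the use of the scaling alternatives to weigh the unfolded protein response list, were chosen after the result was seen; the alternatives themselves, the other splits of the arrays and the lists matched on signal were planned.

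The hybridisation spikes, which no gene comparison uses, read 0.2345 higher on the log2 scale on the R271W arrays than on the controls. The probe sets below the signal filter hold 44 that pass the threshold when no filter is used, 31 higher and 13 lower, among them Slc17a6, a vesicular glutamate transporter gene, at 4.83 ± 6.31 and 36.4 ± 3.92, a gene named after its value was seen.

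The first pattern is the number of called probe sets. The real grouping gave 2940 calls and the highest of the other splits gave 0; only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.

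The second pattern is the lower unfolded protein response list. Its median of -0.31 was set against 10000 lists of the same size matched on mean signal, whose median was -0.05 and 5th percentile -0.16, and 0 of them were as low, which argues against a shift that depends on brightness alone. The list also passed under all 3 scaling alternatives. Median and 75th percentile centring move all log2 changes alike, by about -0.20 and -0.08. Camera sets a list against all other genes, and these centrings move both alike. Such a shift could hardly make or end the call of the list. Under quantile normalization the median of the list was -0.29 and its adjusted p 2.66e-09, the highest of the 3. That result argues against the scaling of the arrays as the only cause. With an estimated correlation (0.0805) the adjusted p of the list was 0.207. Estimating also raised the unadjusted camera p of the immediate early genes from 0.00129 to 0.0225. Their estimated correlation of -0.0179 lay below the preset 0.01, so a higher p under this setting is not by itself a sign of correlated members. Such correlation stays open, as does any effect of the vectors other than the mutant factor, which was not tested. An effect of the mutant on these genes is a hypothesis that none of these tests addresses directly.

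The third pattern is that probe sets that rose were dimmer (median signal 143) than those that fell (347). Compression of bright signals on the R271W arrays stays open. The bright cre and bioD spikes read 0.2577 higher there on the log2 scale, but a larger scaling raises them too and the rise of all spikes had been seen, so this excludes nothing. Set against the dimmer bioB and bioC spikes of the same array, which removes the scaling, they differed by 0.0419 between the groups (3.83 ± 0.0789 and 3.87 ± 0.0669), with arrays that overlapped. A larger scaling of the R271W arrays could raise dim signals, and the probe sets below the filter had medians higher by 0.1057 (1.89 ± 0.0547 and 1.99 ± 0.129). The criterion written for this test, after the array medians had been seen, counted any overlap of the groups against the explanation, and R271W replicate 3 did overlap the controls; that criterion was too strict, since 1 array within the spread excludes nothing, so scaling, compression and a true difference cannot be told apart here.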

How the results depend on the processing

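Of the alternatives below, those for the 4 lists chosen after seeing the data were added afterwards, and their directions held under all of them; the others were planned. The counts of 1596 higher and 1344 lower became 730 and 3132 under median centring. That centring moves every log2 change by about -0.20, which takes calls from higher to lower. With a fold of at least 1.5 the counts were 964 and 506, by construction. Without the intensity trend they were 634 and 431, and the cause was not tested. Leaving out single arrays gave 1000 to 1346 higher (1000 without R271W replicate 2) and 945 to 1327 lower. Lists called higher numbered 0, but 2 under quantile normalization and 1 without the filter. Lists called lower numbered 3, but 5 under median centring and 0 with an estimated correlation. The causes were not tested. An estimated correlation also raised the camera adjusted p of the simulated list, from 1.2e-35 to 0.00711, although its genes were drawn independently. The 0 thus need not reflect correlated members. The oxidative phosphorylation median reversed to 0.1026 under quantile normalization, cause not tested. Other probe sets reversed the sign without passing for Ccne2 (0.2323), Hapln2 (1.0212), Kcnd3 (1.3133 and 0.2397), Lmod3 (-0.4708), Rxrg (-1.1133), Sstr1 (0.2643) and Sypl2 (-0.5082), most at dim signals; the cause was not tested. A further 19 other probe sets of named genes kept the sign but did not pass where the gene's own call did, 29 kept sign and side of the threshold, and 4, of Cacna1d and Kcnj6, differed in sign with neither past it. For single named genes 1639 gene and setting pairs kept direction and side of the threshold, 11 changed sign while passing in neither setting, 160 lost the call and 26 gained it. For lists 352 pairs kept both, 18 changed direction while passing in neither setting, 3 lost and 5 gained the call. With a replicate block 1336 probe sets were higher and 1143 lower. Deviations of same-numbered arrays correlated at -0.0017, 0.0101 and -0.0201, and no array correlated best with its own number. The values thus show no pairing by number, but scatter between arrays could hide a weak one, so a shared batch is not excluded. Dim signals limit folds: the log2 change of Acer1 was 5.53, or 4.69 with a floor and 4.27 with an offset.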

Other observations

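The tests in this part were all chosen after the values of their genes had been seen, so each describes these arrays and none can bear out the hypothesis it came from.

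In 4 other gene groups, written after called genes had been seen, the calls lay mostly in 1 direction, while many members did not pass. Genes of ribosome biogenesis had 31 of 55 tested members that fell and 0 that rose (median log2 fold change -0.42, camera adjusted p = 6.66e-19, and 0.0078 with an estimated correlation), among them the nucleolar genes Gnl3 (-0.88), Nop56 (-0.82) and Dkc1 (-1.13). Genes of protein translocation into the endoplasmic reticulum and N-glycosylation had 24 of 45 that fell and 1 that rose (median -0.30, camera adjusted p = 1.28e-13, and 0.00337 with an estimated correlation), among them Ddost (-0.89) and Sec61a1 (-0.79). Genes of neuronal differentiation had 19 of 37 that rose and 0 that fell (median 0.45, camera adjusted p = 1.41e-09, and 0.00412 with an estimated correlation), among them Map2 (0.88), Dclk1 (1.89) and Nefm (0.79). Genes of fatty acid oxidation had 12 of 26 that rose and 1 that fell (median 0.32, camera adjusted p = 0.000106, and 0.0123 with an estimated correlation), among them Acadm (1.68) and Acads (1.43). These p values were adjusted over the 4 lists alone, those of the fixed lists over 20, so the 2 kinds cannot be set side by side. With an estimated correlation the unadjusted camera p ran from 0.000842 to 0.0123 for these 4 lists. It was 0.0104 for the unfolded protein response list. All 4 kept their direction and passed under quantile normalization and under median and 75th percentile centring. On the same arrays the hybridisation spikes read 0.2345 higher on the log2 scale in R271W cells. The beta-actin ratio of 3' to 5' signal was 1.96 ± 0.099 in R271W cells and 1.82 ± 0.0076 in controls (exact permutation p = 0.1 for each, the smallest this design allows). The poly-A spikes and the other beta-actin and GAPDH ratios overlapped between the groups.

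A hypothesis is that R271W cells may hold less RNA for ribosome biogenesis and for protein translocation and N-glycosylation in the endoplasmic reticulum, and more RNA of neuronal and fatty acid oxidation genes. The 4 lists were written after called genes had been read, so their adjusted p values (such as 6.66e-19 for ribosome biogenesis) overstate the evidence, and a set of arrays not used here would be needed to test it. Mycn and Deptor, which fell, are known regulators of growth, but no test here ties them to these lists.

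Within the unfolded protein response list, 2 of 7 genes of the ATF4 branch fell (mean log2 fold change -0.09 ± 0.26, SD over genes). Of the other 20 tested members 16 fell (-0.51 ± 0.34). These 20 were all the members left over, so they were not picked as chaperone and degradation genes. The exact permutation p of the difference, over genes, was 0.00583. The genes of the ATF4 branch were assigned after the members' values had been seen, and genes are not independent replicates. A difference between that branch and the rest may hold but stays a hypothesis.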
